A study of Mus musculus with 54 samples.

How the data were processed

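RNA was sequenced from mouse ES cells and their derivatives, and 2 deposited tables of gene expression were used, which cover 20 of the 54 samples. The other 34 samples were not analysed here, and the labels gave 1 of them no clear group. These samples are a further RA set, chromatin immunoprecipitation and a capture of chromatin bound by the RNA. Besides other deletions and insertions, the further RA set holds 2 libraries labelled WT and 2 labelled 58 kb KO at each of days 2 and 4. They were thus not used to check the comparison made here. Each of the 8 columns of RA-treated cells is a library: WT-1 and WT-2, KO-i and KO-j at days 2 and 4, from 46C cells kept in serum-free medium with LIF and 2 inhibitors before treatment with 2 µM RA, per the labels' protocols. The LIF and lineage table has 7 columns, of which those of days 0, 2 and 6 are the authors' means over 3, 2 and 3 libraries of the lines CJ7, JF4 and J1 in differing mixtures. Those of day 4 (CJ7), NSC (from 46C, expanded after sorting), NPC (46C) and ME (a line with GFP in T) are single libraries. Groups were taken from the labels, and nothing in them says that libraries of a group came from separate cultures. The p-values therefore measure only the spread between these samples, which may be in part technical. Libraries of 1 name share shifts along chromosomes at both days, described below, and the reported fit does not use the name.

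The values deposited by the authors are FPKM, judged from their range and steps, since no header names the unit. The submitters' processing notes name CASAVA, Bowtie 1.0.0, TopHat2 2.0.11, MACS 1.4.2 and the build mm9 without their role. The program that made the expression values is not given in the sources used here, and both tables include unnamed assembled loci (XLOC), 11592 of 38363 entries for RA and 11621 of 39067 in the other. Of the RA values 8.17% carry more than 6 significant digits and so are sums of several estimates. The RA libraries were not strand-marked and the LIF libraries were stranded, per the labels' protocols, and whether strand was used in counting is not stated. Overlapping or antisense genes are therefore uncertain, as are near-identical family members. Starts are listed from 0 and are given here from 1, since in 8406 genes the listed span equals the gene length of the reference, against 534 genes with 1 added. That reference gene table is of another assembly, GRCm38.p6, and served for names only. Of the RA symbols 21455 are current in it and 1736 are synonyms, among them Gm15055 for Haunt and Gm15051 for Hotairm1, and of the LIF symbols 22114 and 1737. In the LIF set, 11 entries with a repeated symbol were left out. Exact 0 values also occur in genes that every cell uses and may be failed estimates, so such genes are called listed at 0. The tables were normalized separately, and tests stay within a table.

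Depth was estimated from the steps between low values of genes with spans up to 1200 bp. It came to 13.0 and 12.0 M reads for WT-1 and WT-2 and 9.05 and 16.4 for KO-i and KO-j at day 2, and to 10.1, 16.0, 14.9 and 12.3 at day 4. The single libraries of the other table came to 36.5 (day 4), 34.4 (NSC), 40.6 (ME) and 27.7 (NPC), and the authors' means give none. Each estimate rests on the entries that shared the best line of values against span. These were 25 (KO-i at day 4) to 76 (WT-1 at day 2) in the RA libraries. In the single libraries of the other table they were 11 (ME) to 24 (NSC), so the depths are approximate.

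From the RA values log2(FPKM + 1) was computed for 15705 genes with at least 1 FPKM in at least 2 of the 8 libraries, and then limma 3.58.1 in R 4.3.3 was fitted to the 4 groups together with an intensity trend (4 residual and 3.50 prior degrees of freedom). Contrasts were 58 kb KO against WT at each day, their difference, and day 4 against day 2 in each genotype, with Benjamini-Hochberg adjustment and a threshold of 0.05. All adjusted p-values of genes are limma's. The fit was also tested on simulated data with 15705 genes, 100 of them changed by 1 and 100 by 2 log2 units. It recovered 93% and 100% of these for day 2 and 90% and 99% for day 4, with 10 and 14 false among 203 calls each. In the RA libraries at day 4, Gm15055 at -3.93 and Gm15051 at -0.88 log2 units did not pass (limma adjusted p = 0.128 each). The simulated shares are thus not the power of the real comparisons, and a lack of calls does not show a lack of change. Before the data were examined, 20 gene lists, the fits, the alternatives and the rule for named genes were chosen. The lists are the HOXA, HOXB, HOXC and HOXD clusters, Haunt and HOXA neighbours, pluripotency, primed epiblast, neural progenitor and neuron, radial glia and neural stem cell, RA response, mesendoderm, extraembryonic endoderm, trophoblast, fibroblast and feeder, cleavage-stage (Zscan4 and Tcstv) genes, imprinted genes of the Dlk1-Dio3, H19 and like domains, Polycomb, proliferation, stress response and sex of the line. The lists overlap in part, and 247 list members were tested. Lists were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, whose directional p tests whether a list's genes move on balance one way and whose mixed p tests change in either direction, neither against other genes. Where fry is given without a further word, its directional p is meant. Counts of list members are given over all genes and adjusted over the list alone.

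The rule names the HOXA and neighbour genes, up to 10 called genes in each direction with the largest fold change, no overlap between groups and at least 5 FPKM in the higher group (where none passed, the 5 with the smallest p in each direction), and up to 4 members of each other list with the smallest adjusted p. The text names a part of these, more often those whose direction held in all fits, and the others enter the counts of the part on processing. Some genes of the rule are not reported here by name. In single columns the rule takes the 5 largest differences in each direction and up to 4 members of each list. The tests planned for LIF days 2 and 6 could not be fitted, because those columns are means. Differences from day 0 are given instead, over 12511 genes with at least 1 FPKM in at least 2 of the 7 columns. A list's median is placed by its percentile among 10000 random lists, drawn for each member from the 200 genes closest in mean expression. A gene near 0 at day 0 passes this filter only where other columns are higher. Along chromosomes, 9155 named genes with a mean of at least 5 FPKM were used. Windows of 20 genes counted as shifted where the median passed 0.25 at both days, against 1000 shuffles of gene positions. A position that splits a chromosome was picked from the same values, as the cut that best separated the parts on either side. Medians of such a part are therefore those of a selected segment. Alternatives were pseudocounts of 0.1 and 5, no filter and a filter of 5 FPKM, quantile and median-ratio scaling, no trend, each library left out, the compared groups alone, and the library name as a block. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 and R's statmod 1.5.0 served for the rest.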

Results

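Mouse embryonic stem (ES) cells were profiled by RNA sequencing along 2 routes out of pluripotency, and the deposited expression values cover 20 of the 54 samples of the series. In the retinoic acid (RA) set, wild-type (WT) 46C cells, an ES line carrying a GFP reporter in Sox1, and 46C cells with a 58 kb deletion (58 kb KO) of the locus of the long noncoding RNA Haunt were compared. They were treated with 2 µM RA and sampled at days 2 and 4, with 2 libraries per genotype and day. The WT libraries carry the names WT-1 and WT-2 and the knockout libraries the names KO-i and KO-j. The other set followed WT ES cells after withdrawal of LIF, the cytokine that holds ES cells in self-renewal. It gives the authors' means over 3 libraries at day 0, 2 at day 2 and 3 at day 6, and a single library at day 4. Added to these are single libraries of ES-derived mesendoderm (ME), neural progenitor cells (NPC) and neural stem cells (NSC). Haunt lies next to the HOXA cluster, whose homeobox genes set position along the body axis and are induced by RA. The series asks how the RNA and its locus act on HOXA activation. Values are deposited FPKM, and fold changes are log2 differences on the log2(FPKM + 1) scale. The steps between low values put the RA libraries at 9.05 to 16.4 M reads, with the day 2 KO-i library the shallowest. A gene at 1 FPKM thus rests on about 9.05 to 16.4 reads per kilobase. Replicates correlated across genes at r = 0.984 and 0.983 in WT and 0.976 and 0.973 in 58 kb KO at days 2 and 4. These are correlations across genes, which are not independent replicates. On the leading principal component, with 61.3% of the variance, the libraries separated by day. On the next, with 14.1%, KO-i stood apart from the other libraries at both days.

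Haunt, listed as Gm15055 (ENSMUSG00000085412, mm9 chromosome 6, 52052948 to 52062531), was close to absent from the knockout libraries. It measured 135 ± 9.74 FPKM in WT at day 2 and 36.2 ± 6.21 at day 4 (SD, n = 2). It read 1.13 in KO-i and 0 in KO-j at day 2 and 3.08 in KO-i and 0.447 in KO-j at day 4. As a share of the WT mean these were 0.840%, 0, 8.51% and 1.23%. The position of the deletion is not given in the sources used here, so whether the whole measured locus is deleted is not known. At day 2 the fall was 6.54 log2 units (SE 0.499, limma adjusted p = 0.0153).

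At day 2 of RA, genes of the HOXA cluster were lower in the knockout. Hoxa5 (NM_010453, chromosome 6, 52151753 to 52154586) measured 78.8 ± 7.92 FPKM in WT and 22.4 ± 0.392 in 58 kb KO and fell by 1.76 (SE 0.149, adjusted p = 0.0202). Gm15051 (ENSMUSG00000087658, 52106901 to 52112118), the noncoding RNA Hotairm1, measured 477 ± 34.1 and 183 ± 16.0 FPKM and fell by 1.38 (SE 0.120, adjusted p = 0.0202). Since the libraries do not mark strand, reads of overlapping genes cannot be told apart. The values of Gm15051 and of Hoxa3, which has an antisense RNA, may thus include reads of genes that overlap them. So may that of Hoxa5, which lies within the listed spans of Hoxa3 and of the antisense RNA 2700086A05Rik (52151123 to 52163596). Hoxa4 and Hoxa6 also lie within the listed span of Hoxa3. Hoxa3 read 35.7 and 44.3 against 20.1 and 20.4 FPKM (log2 fold change -0.94, adjusted p = 0.35). Hoxa7 was 7.57 ± 1.07 against 2.24 ± 0.647 (-1.41, adjusted p = 0.282), and Hoxa4 was 18.0 ± 3.81 against 11.5 ± 0.597 (-0.59, adjusted p = 0.837). The low genes Hoxa6, Hoxa9 and Hoxa10 had log2 fold changes of -1.19, -0.94 and -1.51, and Hoxa2 differed least, at -0.20. Each HOXA gene named here was thus lower in the knockout mean, and of the list 1 of 9 passed over all genes and 8 of 9 when adjusted over the list alone. The median was -1.19, and camera, which compares a list with the other genes, gave adjusted p = 5.0e-17. With an estimated correlation between genes the adjusted p of this list was 0.0820, and fry, which asks whether genes of a list move on balance one way, gave 0.0121.

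**Figure D1:**
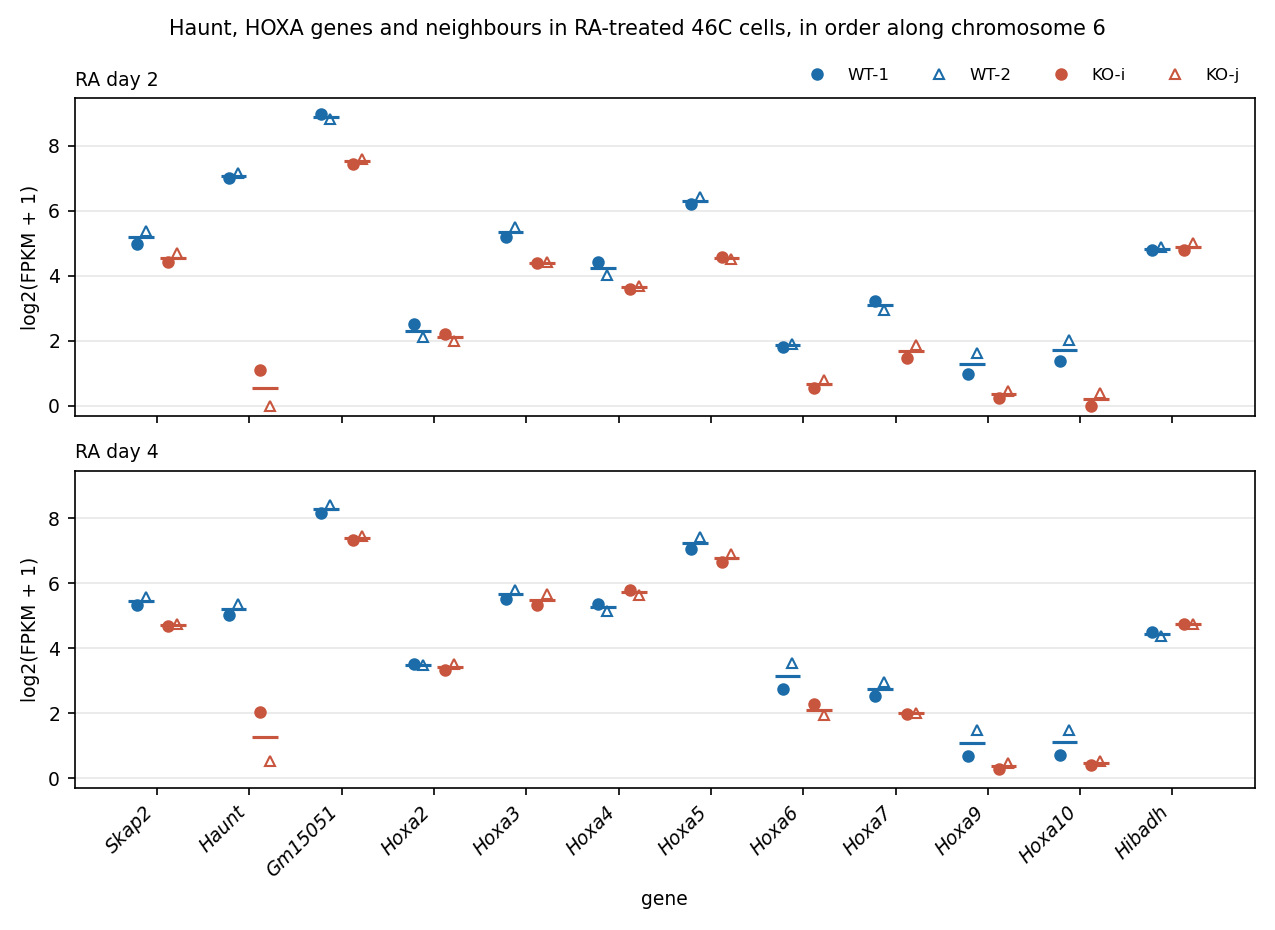
FPKM of genes of the HOXA region in the 8 RA libraries on a log2(FPKM + 1) axis, with a point per library and a bar per group mean, at day 2 and day 4. Haunt (Gm15055) lies at 128 and 142 FPKM in WT at day 2 and at 1.13 and 0 in 58 kb KO, and Hoxa5 at 73.2 and 84.4 against 22.7 and 22.2.

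In the list of Haunt and its neighbours, 2 of 9 genes fell at day 2, Haunt itself (Gm15055) and Gm15051, and 4 when adjusted over the list alone (median -0.38, camera adjusted p = 5.3e-05, with an estimated correlation adjusted p = 0.0971, fry 0.0107). Part of this is the deleted gene, so the list was also tested without it, a choice made after the values were seen. Of the 8 neighbours 1 then fell, and 3 when adjusted over the list alone (median -0.18, camera adjusted p = 0.00874, with an estimated correlation adjusted p = 0.276, fry 0.0210). Skap2, an adaptor gene on the far side of Haunt from the cluster, read 30.8 and 40.7 FPKM in WT and 20.5 and 25.04 in 58 kb KO (-0.62, adjusted p = 0.824). The gene 5730446D14Rik, the antisense RNA Hoxaas2, had -0.66 (adjusted p = 0.64), and 2700086A05Rik, the antisense RNA Hoxaas3, had -0.38. The listed spans of both overlap HOXA genes, so their values carry the limit on strand given above. Tax1bp1, outside the cluster, had +0.28. In KO-j the 389 chromosome 6 genes of at least 5 FPKM were shifted by a median of +0.20 at day 2 and +0.15 at day 4 against the WT mean, and in KO-i by +0.08 and +0.05. In the part of chromosome 6 that holds HOXA, the medians at these days were +0.16 and +0.08 in KO-j. In KO-i they were +0.06 and -0.01. The cuts that bound this part were chosen from these values. At day 2 the lower HOXA values thus stand against a shift in the other direction, small in KO-i. Over all genes 4 of 15705 passed limma's adjusted p of 0.05 at day 2, 1 higher and 3 lower, with 803 at an unadjusted p under 0.05. The groups of 5808 genes (37.0%) did not overlap, where chance gives 33.3%. The gene that rose, the unnamed locus XLOC_012662 (chromosome 2, 117011994 to 117013167), was listed at 0 in both WT libraries and at 7.08 and 5.85 FPKM in KO-i and KO-j at day 2, and at 0 in all 4 libraries of day 4. These calls did not outlast the loss of a library. Without WT-1, WT-2, KO-i or KO-j at day 2, each in turn, 0 genes passed in limma (771, 414, 421 and 1609 at an unadjusted p under 0.05). The adjusted p then lay between 0.187 and 0.280 for Hoxa5, 0.165 and 0.298 for Gm15051 and 0.0767 and 0.263 for Gm15055. Left with 1 library, an arm is assumed in these fits to vary like the other groups.

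Outside the HOXA and neighbour lists, no list had a member that passed over all genes at day 2. The HOXB cluster on chromosome 11 was led by Hoxb6 (102 ± 1.87 against 64.8 ± 6.74 FPKM, log2 fold change -0.66, adjusted p = 0.55) and Hoxb8 (93.9 ± 2.47 against 62.0 ± 7.49, -0.60). Of its genes, 2 of 10 fell when adjusted over the list alone (median -0.12, camera adjusted p = 0.0151, with an estimated correlation adjusted p = 0.276). Pluripotency genes had a median of -0.46 with 0 of 27 passing in either adjustment (camera adjusted p = 4.3e-08, with an estimated correlation adjusted p = 0.427, fry 0.696). Of these genes, Klf5 read 72.0 FPKM in KO-i and 149.9 in KO-j against 190 ± 49.5 in WT, and Klf2 21.2 and 40.6 against 53.4 ± 8.20. Both encode Krüppel-like factors of the naive network. Primed epiblast genes had a median of -0.39 with 0 of 9 passing in either adjustment (camera adjusted p = 0.000291, with an estimated correlation adjusted p = 0.427). Among them Pou3f1 stood at 5.25 FPKM in KO-i and 9.37 in KO-j against 11.7 ± 1.94. Camera also put 5 lists below the other genes at adjusted p 0.0151 to 0.037, each with 0 members passing and a median of -0.25 to -0.05: HOXC, neural progenitor, radial glia, mesendoderm and extraembryonic endoderm (adjusted p = 0.427 to 0.601 with an estimated correlation). The remaining lists, HOXD, RA response, trophoblast, fibroblast and feeder, cleavage-stage, imprinted, Polycomb, proliferation, stress response and sex of the line, gave camera adjusted p of 0.169 to 0.935. In several of these the median and the mean lay within 0.08 of 0 with opposite signs, as for trophoblast (median -0.01, mean 0.000394), imprinted (+0.01, -0.04), Polycomb (-0.02, +0.03), proliferation (+0.01, -0.00422) and stress response (+0.07, -0.02). Camera pointed down for the fibroblast list, whose median and mean were +0.02 and +0.05. For HOXD camera pointed down and fry up.

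At day 4 no gene passed between 58 kb KO and WT in limma (0 genes, with 2263 at an unadjusted p under 0.05; the groups of 7321 genes, 46.6%, did not overlap, where chance gives 33.3%). Among the lists that camera at the preset correlation placed apart were those of extraembryonic endoderm and trophoblast genes, with lower medians in the knockout. Gata4, a transcription factor of primitive endoderm and heart, was 45.5 ± 2.98 FPKM in WT and 24.6 ± 1.21 in 58 kb KO (n = 2 each, log2 fold change -0.86, SE 0.15, adjusted p = 0.134). Col4a1 and Col4a2, the basement membrane collagens made in quantity by parietal endoderm, were 576 ± 18.3 against 301 ± 39.3 and 341 ± 19.7 against 182 ± 23.3 (-0.94 and -0.91, adjusted p = 0.168 and 0.163). The matrix protein gene Sparc was 664 ± 70.8 against 366 ± 40.9 (-0.86, adjusted p = 0.187). Col4a1 and Sparc are named here by choice after their values were seen. The apolipoprotein gene Apoa1 and the thyroxine carrier gene Ttr are both active in visceral endoderm. Apoa1 read 8.69 and 23.2 FPKM against 0.693 and 0.634, and Ttr 7.05 and 8.96 against 1.53 and 1.70 (-3.20 and -1.78, adjusted p = 0.128 each). Of 20 extraembryonic endoderm genes 14 fell when adjusted over the list alone and 0 over all genes, with a median of -0.84 and a camera adjusted p of 3.5e-10. With an estimated correlation the adjusted p was 0.231, and fry gave 0.0223. Of 8 trophoblast genes 5 fell when adjusted over the list alone and 0 over all genes (median -0.72, camera adjusted p = 0.000903, with an estimated correlation adjusted p = 0.256, fry 0.110). Those with the smallest p were the simple-epithelium keratins Krt8 (125 ± 40.8 against 42.2 ± 19.3 FPKM, -1.59, adjusted p = 0.165), Krt18 (-1.20, adjusted p = 0.173) and Krt7 (-0.73, adjusted p = 0.182) and the homeobox gene Cdx2 (1.23 and 2.58 against 0.104 and 0.464 FPKM).

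**Figure D2:**
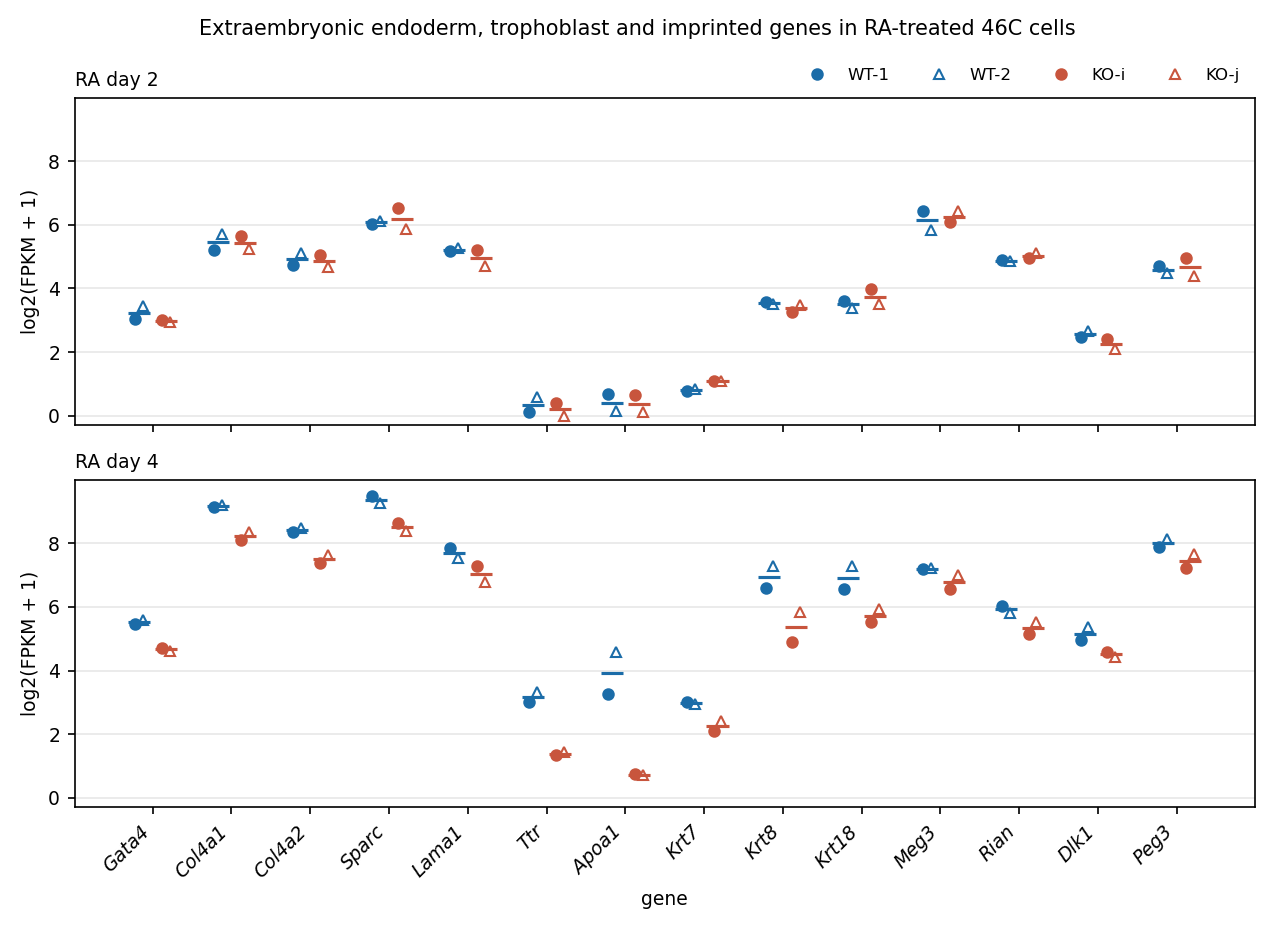
FPKM of 14 extraembryonic endoderm, keratin and imprinted genes in the RA libraries at day 2 and day 4 on a log2(FPKM + 1) axis, with a point per library and a bar per group mean (n = 2). At day 4 the 58 kb KO points lie below the WT points for Gata4 (25.5 and 23.7 against 43.4 and 47.6 FPKM) and Ttr (1.53 and 1.70 against 7.05 and 8.96).

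Imprinted genes formed another group of lower values at day 4. Of 8, 6 fell when adjusted over the list alone and 0 over all genes, and all 8 had a negative fold change. The list stood apart in camera (median -0.62, camera adjusted p = 1.6e-06, with an estimated correlation adjusted p = 0.256, fry 0.0353). The maternally expressed noncoding RNAs Rian and Mirg of the Dlk1-Dio3 domain were 60.1 ± 6.87 against 39.8 ± 7.49 FPKM and 19.8 ± 3.88 against 11.2 ± 0.456 (-0.59 and -0.76, adjusted p = 0.192 and 0.194). The paternally expressed Dlk1 of that domain was 35.2 ± 6.93 against 21.8 ± 2.02 (-0.66), and Airn, the noncoding RNA of the Igf2r domain, was 8.58 ± 0.538 against 4.29 ± 0.397 (-0.86, adjusted p = 0.165). Mesendoderm genes had a median of -0.52, with 4 of 11 falling when adjusted over the list alone (camera adjusted p = 0.00150, with an estimated correlation adjusted p = 0.256). Lhx1 stood at 16.5 ± 5.60 against 4.47 ± 0.275 FPKM (-1.64, adjusted p = 0.128) and the receptor gene Pdgfra at 19.6 ± 3.79 against 9.85 ± 0.567 (-0.91, adjusted p = 0.177). Neural progenitor genes had 5 of 19 falling when adjusted over the list alone (median -0.34, camera adjusted p = 0.00273, with an estimated correlation adjusted p = 0.360). They included Lhx1. RA response genes went both ways, with 4 of 20 rising and 5 falling when adjusted over the list alone (median 0.00221, camera adjusted p = 0.53). Stra8, a meiosis gatekeeper, read 834 and 395 FPKM in WT against 2315 and 1429.5 in 58 kb KO (+1.66, adjusted p = 0.206). Cyp26b1, which breaks down RA, was 120.2 ± 6.65 against 224 ± 75.6 (+0.85). Stra6, a retinol transporter gene, was 130.3 ± 33.8 against 68.1 ± 3.85 (-0.90, adjusted p = 0.165).

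Haunt and most HOXA genes named here stayed lower or even at day 4. Gm15055 was 3.93 log2 units lower (SE 0.50, adjusted p = 0.128), and Gm15051 was 314 ± 38.8 against 169 ± 9.49 FPKM (-0.88, adjusted p = 0.128). Hoxa5, at 152 ± 27.7 against 109 ± 13.4 FPKM (-0.48, adjusted p = 0.249), and Hoxa3, at 49.9 ± 7.23 against 44.6 ± 7.07 (-0.16), had smaller values of the difference than at day 2. Hoxa4 read 55.1 and 48.9 in the knockout against 40.6 and 34.7 (+0.46, adjusted p = 0.278). Hoxa6 had -1.04, Hoxa7 -0.76, Hoxa9 -0.73, Hoxa10 -0.63 and Hoxa2 -0.09. Over the list 0 of 9 passed over all genes, and adjusted over the list alone 4 fell and 1 rose. Camera passed the list (median -0.63, camera adjusted p = 0.00273, with an estimated correlation adjusted p = 0.256, fry 0.110). The median rested on single WT libraries: it was -0.98 without WT-1 and -0.27 without WT-2 at day 4. Of Haunt and its neighbours 0 of 9 passed over all genes and 4 fell when adjusted over the list alone (median -0.42, camera adjusted p = 0.0425, with an estimated correlation adjusted p = 0.256, fry 0.0223). Without Haunt 3 of 8 fell when adjusted over the list alone, and camera did not pass (median -0.13, camera adjusted p = 0.263, with an estimated correlation adjusted p = 0.412, fry 0.0486). Skap2 stood at 43.1 ± 5.29 against 25.4 ± 0.840 FPKM (-0.74, adjusted p = 0.173) and 5730446D14Rik at -0.73. In the HOXB cluster 1 rose and 1 fell of 10 when adjusted over the list alone (median +0.24, camera adjusted p = 0.0566). Hoxb1 stood at 27.7 ± 14.7 against 52.7 ± 8.27 FPKM (+1.00, adjusted p = 0.266), Hoxb2 at +0.45 (adjusted p = 0.192) and Hoxb13 at -1.31 (adjusted p = 0.2).

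The smallest p-values at day 4, none past the threshold (adjusted p = 0.128 for each), began upward with 2 unnamed loci, Bpnt1 (10.8 ± 0.369 against 21.6 ± 3.35 FPKM, +0.94) and Cecr5 (11.9 ± 0.00332 against 19.8 ± 0.335, +0.69), which lie on chromosomes 1 and 6. Downward they began with Gm10664 (12.2 ± 0.271 against 2.21 ± 0.512, -2.06) and Fam129b (60.1 ± 3.84 against 31.1 ± 0.831, -0.93). In KO-i the 482 chromosome 1 genes of at least 5 FPKM were shifted by a median of +0.31 at day 2 and +0.30 at day 4. In KO-j the 71 of them from position 177531509 on, a cut chosen from these values, were shifted by +0.47 at both days. Without KO-j at day 4, 7 genes passed in limma, and without WT-1 at day 4, 1 gene. Radial glia (median -0.18) and proliferation genes (-0.15) lay below the other genes in camera at adjusted p = 0.0421 each (with an estimated correlation adjusted p = 0.360 each), with 1 of 15 and 0 of 16 falling when adjusted over the list alone. In the remaining lists camera gave adjusted p of 0.221 to 0.921: HOXC, HOXD, pluripotency (1 of 27 rising when adjusted over the list alone, Dppa4, at 12.3 and 10.2 FPKM against 18.6 and 17.1), primed epiblast, fibroblast and feeder, cleavage-stage, Polycomb, stress response (1 of 15 rising when adjusted over the list alone) and sex of the line. For primed epiblast genes the median (+0.09) and mean (-0.02) differed in sign, and for the RA response and Polycomb lists camera pointed down over medians above 0.

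**Figure D3:**
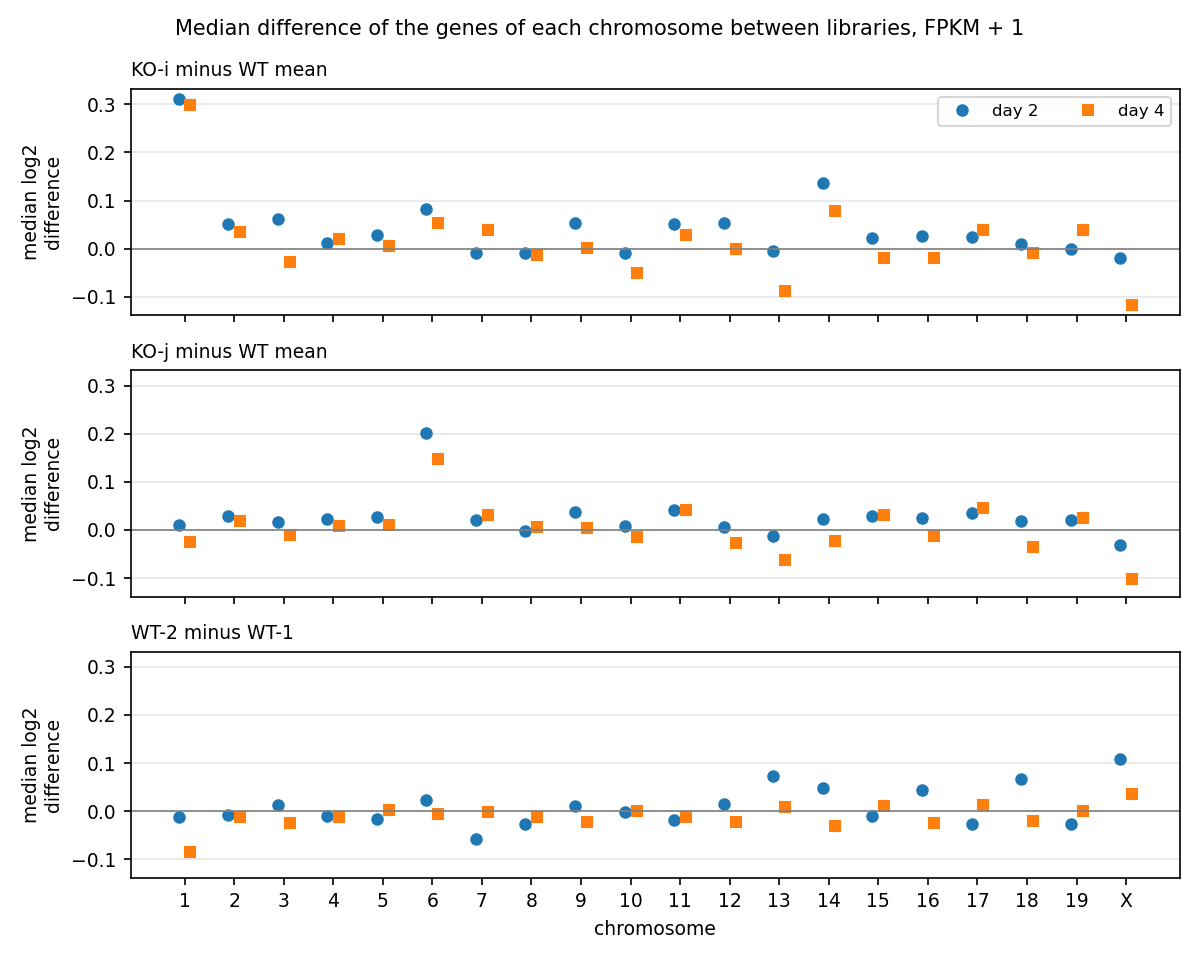
Median log2(FPKM + 1) difference of genes of at least 5 FPKM by chromosome, for KO-i and KO-j against the WT mean and for WT-2 against WT-1, at day 2 and day 4. KO-i lies at +0.31 and +0.30 on chromosome 1 and KO-j at +0.20 and +0.15 on chromosome 6.

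The difference between the genotype effects at days 2 and 4 was tested as an interaction. No gene passed (0 in limma, 873 at an unadjusted p under 0.05, adjusted p from 0.71). Hence no gene is called as responding differently by day. Among the smallest unadjusted p-values were Hoxa5 (+1.29, SE 0.21, unadjusted p = 0.00038), with log2 fold changes of -1.76 at day 2 and -0.48 at day 4, Fam129b (-0.84), Gm10664 (-1.83) and XLOC_012662. Over the HOXA list 0 of 9 passed over all genes and 3 rose when adjusted over the list alone (median +0.65, camera adjusted p = 4.5e-05), and in the HOXB list 2 of 10 did (median +0.43, camera adjusted p = 0.000375), with an estimated correlation adjusted p = 0.192 in both. Extraembryonic endoderm genes had a median of -0.64 with 2 of 20 falling when adjusted over the list alone (camera adjusted p = 7.5e-07, with an estimated correlation adjusted p = 0.192). Trophoblast genes had -0.91 with 3 of 8 falling (camera adjusted p = 0.0012, estimated-correlation adjusted p = 0.341), and imprinted genes -0.64 with 0 of 8 (camera adjusted p = 1.9e-05, estimated-correlation adjusted p = 0.192). Pluripotency and primed epiblast genes had medians of +0.48 and +0.39 with 0 members passing (camera adjusted p = 0.00237 and 0.0215, estimated-correlation adjusted p = 0.583 and 0.511). The other 13 lists gave camera adjusted p of 0.0501 to 0.982, with median and mean of opposite sign for HOXC (-0.000543, +0.03). The directional p of fry passed 0 lists. Its mixed p passed the HOXA, HOXB, extraembryonic endoderm and trophoblast lists (fry mixed adjusted p = 0.0434 each).

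From day 2 to day 4 of RA, pluripotency genes were mostly lower in WT cells and extraembryonic endoderm and RA response genes mostly higher. Dppa5a, an RNA-binding protein gene of ES cells, fell from 988 ± 88.2 to 79.9 ± 4.24 FPKM (log2 fold change -3.61, limma adjusted p = 0.000381). The pluripotency factor gene Nanog fell from 147 ± 41.5 to 11.5 ± 0.964 (-3.55, adjusted p = 0.00451). Igfbp5, an IGF-binding protein gene, rose from 4.22 ± 0.788 to 298 ± 39.9 FPKM (+5.84). The smooth muscle genes Acta2 and Tagln rose by 5.43 and 5.38, Osr1, a factor of intermediate mesoderm, by 5.03, the keratin gene Krt19 by 5.02 and the BMP target Id3 by 4.68, with adjusted p between 0.000302 and 0.00159. Besides Nanog and Dppa5a, the genes that fell most included Tcf15 (-3.98), the RA- and Wnt-responsive homeobox gene Cdx1 (-3.96), Etv4 (-3.56) and Lefty1 (-4.36, adjusted p = 0.0134). The call of Lefty1 ended without any 1 of the WT libraries (adjusted p = 0.0515 without WT-1 and 0.0803 without WT-2 at day 2, 0.0555 and 0.0769 at day 4). In all, 2260 genes rose and 1713 fell, 862 and 819 of them by more than 2-fold on this scale. The groups of 10808 genes (68.8%) did not overlap, where chance gives 33.3%. The count of 3973 was 1876 without WT-1 and 1742 without WT-2 at day 2, and 1873 without WT-1 and 1474 without WT-2 at day 4. It was 38 without both WT-2 libraries. The 53 X-linked genes from position 146832316 on were higher in WT-2 than in WT-1 by medians of 0.99 and 0.89 at the 2 days. For the 228 other X-linked genes the medians were 0.02 and -0.03. The cut was chosen from these values.

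By group, 20 of 27 pluripotency genes fell in WT (22 when adjusted over the list alone, median -2.01, camera adjusted p = 2.2e-11, with an estimated correlation adjusted p = 0.285). So did 6 of 9 primed epiblast genes (8, with 1 rising, when adjusted over the list alone, median -1.05), such as Pou3f1 (-3.03) and Dnmt3l (-2.20). Falls were also called in 9 of 10 cleavage-stage genes (9 when adjusted over the list alone, median -2.30), such as Tcstv1 (-2.49), and 7 of 16 proliferation genes (7, median -0.35). Of 20 extraembryonic endoderm genes 16 rose and 1 fell (18 and 1 when adjusted over the list alone, median +2.12, camera adjusted p = 2.5e-09, with an estimated correlation adjusted p = 0.285). Col4a1 stood at +3.70, Col4a2 at +3.50, Sparc at +3.30 and Gata4 at +2.30. Of 8 trophoblast genes 5 rose, including Krt18 (+3.42), Krt8 (+3.41) and Gata3 (+3.42), and 1 fell (6 and 1 when adjusted over the list alone, median +2.09). Of 20 RA response genes 11 rose and 3 fell (12 and 4 when adjusted over the list alone, median +0.82). The orphan receptor genes Nr2f2 (+3.63) and Nr2f1 (+3.49) and the RA receptor gene Rarb (+2.27) rose. Of 8 imprinted genes 6 rose (7 when adjusted over the list alone, median +1.44), among them Peg3 (+3.42), Dlk1 (+2.60), Airn (+2.22) and Igf2 (+1.81). Radial glia genes had 8 of 15 rising and 2 falling in both adjustments (median +0.82), with Sox9 at +2.19 and Egfr at +1.29. HOXC genes had 4 of 7 rising (4 rising and 1 falling when adjusted over the list alone, median +0.91), with Hoxc8 at +2.32. Camera placed these 10 lists apart from the other genes at adjusted p of 2.2e-11 to 0.0253, and with an estimated correlation each had adjusted p = 0.285. The other 10 did not pass camera (adjusted p 0.14 to 0.976). In these, HOXA had 4 of 9 rising (median +0.31), HOXB 4 rising and 1 falling of 10 (5 and 2 when adjusted over the list alone), HOXD 3 of 6 and Haunt with its neighbours 2 rising and 3 falling. The counts were, for neural progenitor genes 9 rising and 5 falling of 19 (9 and 6), mesendoderm 4 and 3 of 11 (5 and 3), fibroblast and feeder 6 and 2 of 11, Polycomb 1 and 3 of 14, stress response 2 and 4 of 15 (4 and 5) and sex of the line 0 of 3. In parentheses are counts adjusted over the list alone where they differ. Camera pointed down for the stress and sex lists, whose medians were +0.21 and +0.08.

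Within the HOXA region in WT, Hoxa4 (+1.03, adjusted p = 0.00448), Hoxa5 (+0.94, adjusted p = 0.00517) and Hoxa2 (+1.18, adjusted p = 0.00373) rose from day 2 to day 4, as did Hoxa6 (+1.29, adjusted p = 0.0152) and the antisense RNA 2700086A05Rik (+2.21, adjusted p = 0.00216). The listed span of 2700086A05Rik holds Hoxa5 and Hoxa6, and the libraries do not mark strand. Its rise thus cannot be told apart from reads of these genes. Haunt fell by 1.87 (adjusted p = 0.0307) and Gm15051 by 0.61 (adjusted p = 0.0109). The call of Haunt ended without WT-1 or WT-2 at day 2 (adjusted p = 0.105 and 0.132) or day 4 (0.138 and 0.0945). That of Gm15051 ended without WT-1 at day 2 (0.0697) or day 4 (0.0691), and that of Hoxa6 without WT-1 or WT-2 at day 2 (0.0774 and 0.0696) or WT-2 at day 4 (0.0779). Hoxb1, which is induced early by RA, fell from 105 ± 23.0 to 27.7 ± 14.7 FPKM (-1.97, adjusted p = 0.00615), while Hoxb3 (+1.21) and Hoxb9 (+0.81) rose.

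The knockout cells made a similar passage, with 1576 genes rising and 1226 falling from day 2 to day 4 (498 and 556 by more than 2-fold). The groups of 9397 genes, 59.8%, did not overlap, where chance gives 33.3%. Acta2 and Tagln rose by 4.96 and 4.69, Igfbp5 by 4.31, Id3 by 3.67, the cardiac actin gene Actc1 by 3.62 and the myosin light chain gene Myl9 by 3.38 (adjusted p 0.00198 to 0.00719). Dppa5a (-3.43), Cdx1 (-3.36) and the peroxisomal oxidase gene Pipox (-3.19) were among those that fell most. Of the genes that rose, 1240 were shared with WT, where independent lists would share 226.8, and of those that fell 919, where independent lists would share 133.7. In 1 gene the directions were opposite. WT and KO share no library in these comparisons. Their fit does share the estimate of each gene's spread, so the calls are linked and the counts for independent lists are no strict baseline. The HOXA genes Hoxa5 (22.4 ± 0.392 to 109 ± 13.4 FPKM, +2.22, adjusted p = 0.00161), Hoxa4 (+2.08, adjusted p = 0.00161), Hoxa3 (+1.09, adjusted p = 0.00732) and Hoxa2 (+1.30, adjusted p = 0.00585) rose. So did Hoxa6 (+1.44, adjusted p = 0.0161), whose call ended without KO-i at day 2 (adjusted p = 0.0604) or day 4 (0.0760). Of the HOXA list 5 of 9 rose in both adjustments (median +1.09). Of HOXB 7 of 10 rose and 1 fell (8 and 1 when adjusted over the list alone, median +0.87), with Hoxb9 at +1.19 and Hoxb2 at +0.73. Of HOXC 4 of 7 rose (5, median +0.75). Extraembryonic endoderm genes rose again, 11 of 20 with 1 falling (14 and 1 when adjusted over the list alone, median +1.04), with Col4a1 at +2.80, Col4a2 at +2.64, Sparc at +2.32 and Gata4 at +1.70. The count of 2802 was 1667 without KO-i and 990 without KO-j at day 2, and 1124 without KO-i at day 4. It was 757 in the compared groups alone, 875 without both KO-i libraries and 713 without both WT-2 libraries.

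Further lists moved in the knockout as follows. Of pluripotency genes 15 of 27 fell (20 with 1 rising when adjusted over the list alone, median -1.51), with Dppa4 at -1.36 and Fbxo15 at -2.84. Of primed epiblast genes 4 of 9 fell and 1 rose in both adjustments (median -0.57), with Pou3f1 at -2.29. Of cleavage-stage genes 7 of 10 fell (10, median -1.87), and of proliferation genes 8 of 16 (10, median -0.44), such as Top2a (-0.72). RA response genes had 10 of 20 rising and 2 falling (11 and 2, median +0.54), with Nr2f2 at +2.67, Cyp26b1 at +2.34 and Rarb at +1.72. Trophoblast genes had 5 of 8 rising and 1 falling (median +1.4), with Gata3 at +2.51, Krt18 at +1.98 and Krt7 at +1.16, and imprinted genes 4 of 8 rising and 1 falling (median +0.80), with Peg3 at +2.76 and Dlk1 at +2.26. Radial glia genes had 7 of 15 rising and 1 falling (8 and 2, median +0.66), and fibroblast and feeder genes 7 of 11 rising and 1 falling (7 and 2, median +0.85), with Fn1, for fibronectin, falling by 0.59. Numbers in parentheses are those adjusted over the list alone, given where they differ. Camera passed these and the HOXA, HOXB, HOXC and extraembryonic endoderm lists, 13 in all, at adjusted p of 6.7e-11 to 0.0243. With an estimated correlation the adjusted p was 0.177 to 0.330. The other 7 lists, HOXD (1 rising), Haunt with its neighbours (3 rising), neural progenitor (6 rising, 3 falling, 6 and 4 when adjusted over the list alone), mesendoderm (2 and 3), Polycomb (2 and 3, then 2 and 4), stress response (4 and 3, then 5 and 4) and sex of the line (0), gave camera adjusted p of 0.122 to 0.982. Median and mean had opposite signs for stress response (-0.07, +0.14) and sex (+0.02, -0.15).

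Over the days after LIF withdrawal, the values went from a naive through a primed to a mesendodermal profile. Since these are the authors' means and a single library, no test could be run and the differences have no replicate check. The mixture of the lines CJ7, JF4 and J1 also differs between days, with CJ7 alone at day 4 and no J1 at day 0. Differences between days thus cannot be told apart from differences between lines. The naive factor genes Klf4, Esrrb and Nr0b1 stood at 43.4, 85.5 and 71.3 FPKM at day 0 and at 2.20, 4.71 and 2.34 at day 2, and the primordial germ cell gene Dppa3 at 183 and 7.66. Pou5f1, the Oct4 gene, held longer, at 997 FPKM at day 0, 885 at day 2, 579 at day 4 and 177 at day 6. The median over 26 pluripotency genes was -1.62 at day 2, -3.38 at day 4 and -2.70 at day 6, each at percentile 0 among 10000 random lists of matched expression. Primed epiblast genes were above day 0 at day 2 (median +1.42 over 10 genes, percentile 100, 6 of them more than 2-fold higher). The epiblast growth factor gene Fgf5 went from 1.18 to 19.5 FPKM, Pou3f1 from 4.58 to 21.8 and Otx2 from 4.65 to 15.6. At day 6 this median was -0.19 (percentile 10.3). Mesendoderm genes had medians of +0.63, +3.57 and +2.94 over 17 genes at days 2, 4 and 6 (percentile 100 each). Members near 0 at day 0 pass the filter only through columns where they are higher, which in part sets these values. The mesoderm master gene T stood at 18.4, 204 and 56.1 FPKM at these days, Mixl1 from day 0 to day 6 at 0.133, 1.04, 67.1 and 22.7, and Eomes at 2.99, 13.0, 67.6 and 29.7. At day 6 Hand1, a factor of heart and extraembryonic mesoderm, reached 268 FPKM from 3.84 and the RA-degrading enzyme gene Cyp26a1 92.3 from 1.76. Amot reached 82.0 from 1.99, Msx2 76.2 from 2.07, the growth factor gene Igf2 358 from 13.4 and Krt8 1619 from 128. Trophoblast, fibroblast and feeder, and extraembryonic endoderm lists had day 6 medians of +2.78, +2.07 and +1.81 (percentile 100 each). More than 2-fold apart from day 0 were 416 higher and 423 lower genes at day 2, 586 and 722 at day 4 and 1113 and 589 at day 6, of 12511.

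**Figure D4:**
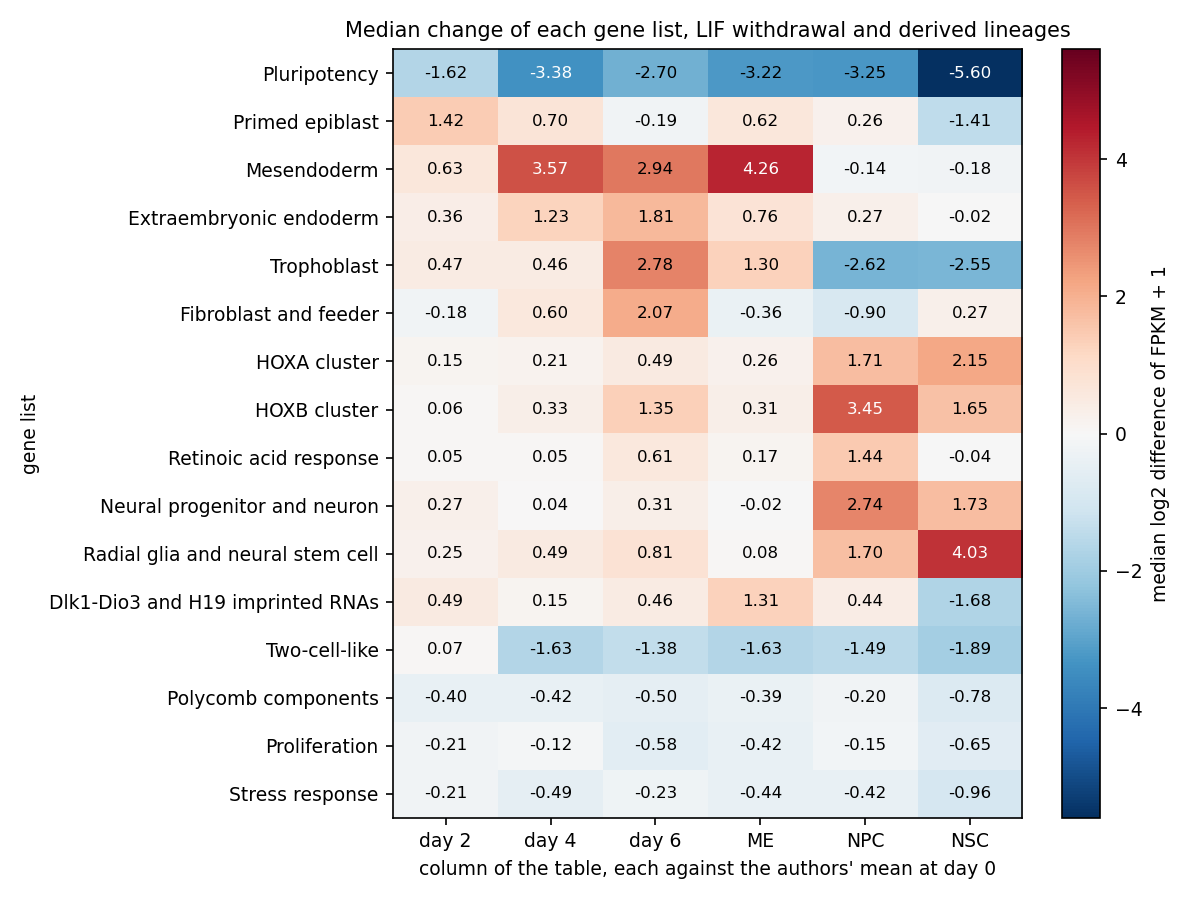
Median log2(FPKM + 1) difference from day 0 for gene lists in the LIF withdrawal and lineage columns, as a heat map with lists in the vertical and samples in the horizontal direction. Pluripotency lies below 0 throughout, from -1.62 at day 2 to -5.60 in NSC, and mesendoderm is highest in ME, at +4.26.

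The lineage libraries, sorted for reporters of T (ME) or Sox1 (NPC, and NSC before their expansion), each carried the genes of their name, T and Sox1 being no finding. List members near 0 at day 0 pass the filter only through columns where they are higher. Medians, counts and percentiles of the lists that are higher here are therefore set in part by the filter. The mesendoderm list also includes T. ME had a mesendoderm median of +4.26 (15 of 17 genes more than 2-fold higher, percentile 100), with Mixl1 at 115 FPKM, Eomes at 90.8 and Cyp26a1 at 139. Mesp1 and Msgn1, of early and presomitic mesoderm, stood at 37.7 and 47.4. NSC had a radial glia median of +4.03, with all 15 genes past the filter, of 20 in the list, more than 2-fold higher. It reached 1227 FPKM for the brain fatty acid binding protein gene Fabp7 (0.477 at day 0), 1885 for the growth factor gene Ptn (1.37), 1258 for Serpine2 (9.81) and 211 for the oligodendrocyte lineage gene Olig2 (12.0). NPC had a neural progenitor median of +2.74 (15 of 19 past the filter more than 2-fold higher, of 30 in the list) and an RA response median of +1.44. The retinoid binding protein genes Crabp1 and Crabp2 stood at 1129 and 886 FPKM (11.1 and 9.63 at day 0), Irx3 at 91.5 and Pax6 at 55.9 (17.7 in NSC). Crabp2 was at 0.308 in NSC. The pluripotency median was -5.60 in NSC, -3.25 in NPC and -3.22 in ME, where Pou5f1 remained at 0.391, 91.0 and 486 FPKM. Trophoblast medians were -2.55 in NSC and -2.62 in NPC, with Krt8 at 0.761 and 5.15 FPKM, and +1.30 in ME. The imprinted list had -1.68 in NSC, with Meg3 at 0.147 and Rian at 0.122 FPKM against 15.3 and 16.3 at day 0, and +1.31 in ME. NSC stood farthest from day 0, with 2020 genes more than 2-fold higher and 1416 lower, against 1346 and 1016 in NPC and 853 and 855 in ME.

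Haunt and single genes near it differed between these states. Haunt was 53.7 FPKM at day 0, 4.13 at day 2, 0.175 at day 4 and 0.266 at day 6 of LIF withdrawal, listed at 0 in ME, and 66.3 in NSC and 18.5 in NPC. In this table genes used by every cell, such as Sept7 and Nolc1, are also listed at 0 in some columns. Gm15051 was 1.48, 13.5, 2.91 and 11.3 FPKM from day 0 to day 6, 117 in NSC, 16.0 in NPC and 8.68 in ME. Of the HOXA genes, Hoxa2 went from 0.0810 at day 0 to 16.7 FPKM in NSC and 24.6 in NPC, and Hoxa3 from 0.0210 to 9.13 and 3.56, and at day 6 of LIF withdrawal both were under 0.5. The HOXA median over the 5 of 11 genes past the filter was +2.15 in NSC (percentile 99.9) and +1.71 in NPC (percentile 99.98). It was +0.15, +0.21 and +0.49 at days 2, 4 and 6 and +0.26 in ME. That of HOXB over 6 of 10 genes was +3.45 in NPC, +1.65 in NSC and +1.35 at day 6. HOX genes near 0 at day 0 pass the filter only through columns where they are higher. These medians and percentiles are therefore set in part by the filter. Skap2 was 28.3 FPKM at day 0 and 150 in NSC. The remaining lists had medians between -2.60 and +0.08 in these columns. They were, for cleavage-stage genes, -1.89 to +0.07, Polycomb -0.78 to -0.20, proliferation -0.65 to -0.12, stress response -0.96 to -0.21, sex of the line -2.60 to -0.20, and Haunt with its neighbours -0.33 to +0.08. The last list was at percentile 1.02 at day 2, and without Haunt at 2.22 (median -0.29). There was no HOXC gene and 1 HOXD gene measured above the filter. The LIF and RA tables were normalized separately, so levels are not set across them.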

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

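The tests of a uniform lag and of a single knockout library were chosen only after the result was seen, and the test of the normalization before. The results below were singled out because the effect of the 58 kb deletion differed between day 2 and day 4 in the interaction. The rule was a limma p under 0.05 when adjusted over the gene's list alone. None passed when adjusted over all genes (limma, 0 genes, adjusted p from 0.71, with 873 genes at an unadjusted p under 0.05).

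In the HOXA cluster the interaction was +1.29 for Hoxa5 (unadjusted p = 0.00038), +1.05 for Hoxa4 (0.0019) and +0.78 for Hoxa3 (0.01), each with lower knockout values at day 2. The day 4 values of Hoxa4 were 55.1 and 48.9 FPKM in the knockout against 40.6 and 34.7 in WT. In the HOXB cluster it was +0.91 for Hoxb6 (unadjusted p = 0.0015), which read 60.1 and 69.6 FPKM in the knockout against 104 and 101 in WT at day 2 and 87.8 and 106 against 87.5 and 74.5 at day 4, and +0.56 for Hoxb2. The visceral endoderm genes Apoa1 and Ttr had -3.17 and -1.64, and the keratin genes Krt18, Krt8 and Krt7 had -1.44, -1.43 and -1.02.

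The pattern weighed here is that of extraembryonic endoderm and trophoblast genes with lower values in the knockout at day 4. A uniform lag of the knockout cells at day 4 is argued against, because at that day the median deficit was 39.5% of the WT change for extraembryonic endoderm genes and 34.5% for trophoblast genes, while the pluripotency list held back -5.20% of its own. From day 2 to day 4, however, the pluripotency median changed by -1.51 in the knockout and -2.01 in WT, from a knockout median of -0.46 against WT at day 2. A slower passage from another starting state was not tested and stays open. The authors' normalization is argued against, because after rescaling by the median ratio the extraembryonic endoderm median was -0.88 instead of -0.84. Dependence on a single knockout library is argued against by medians of -0.78 and -0.79 in the 2 libraries. Both medians are taken against the same WT mean, so dependence on a single WT library was not tested. An effect of the deletion on these genes may account for the pattern, as may differences between the lines as picked and grown, and with 2 knockout and 2 WT libraries neither was tested.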

How the results depend on the processing

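The counts of called genes, the HOXA medians, the list tests, the genes of the rule in the RA table and the list medians of the LIF and lineage table were recomputed, changing 1 choice at a time. Other values were not. Dropping the genes of chromosomes 1, 6 and X or both libraries named KO-i or WT-2, subtracting the chromosome 6 shift, taking Haunt out of its list, and the alternatives for LIF and lineage medians other than pluripotency at day 6 were chosen after seeing the data. For 58 kb KO against WT at day 2, 4 genes passed in the reported limma fit. The count was 7 with no filter, of which 1 was among those 4, and 0 in the compared groups alone (730 at an unadjusted p under 0.05). It was 1 without chromosomes 1, 6 and X, 1 without both KO-i libraries and 0 without both WT-2 libraries (337 at an unadjusted p under 0.05). Leaving out a library in turn gave 0 to 0. The calls of Gm15055 and XLOC_012662 ended at pseudocount 0.1. At day 4 the count of 0 became 1 at pseudocount 0.1, 7 at pseudocount 5, 1 with no filter, 1 without both KO-i libraries and 0 to 7 without a library. For the interaction it became 5 with no filter, 1 in limma without the trend and 0 to 1 without a library. For day 4 against day 2 in WT, 3973 became 1474 to 1876 without a library and 38 without both WT-2 libraries. In 58 kb KO, 2802 became 1596 with no filter, 757 in the compared groups alone, 875 and 713 without both KO-i or both WT-2 libraries, and 990 to 2156 without a library. A library left out of a group of 2 leaves a lone sample that is assumed to vary like the other groups. For these changes the cause was not tested. The other alternatives kept each count within 1.5 times.

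The HOXA median at day 2 was -1.74 and -0.50 at pseudocounts 0.1 and 5 against -1.19, as the scale implies, and -1.32 to -1.05 without a library. At day 4 it was -0.92 and -0.23 at these pseudocounts against -0.63, -0.98 to -0.27 without a library and -0.73 less the chromosome 6 shift. The shift taken off is the median over the whole chromosome, and the part that holds HOXA was shifted less. The pluripotency median at LIF day 6, -2.70, was -3.06 and -2.31 at pseudocounts 0.1 and 5 and -2.78 after quantile normalization. Over all 108 list medians of that table, 6 turned sign in an alternative, the largest of them 0.180 in size as reported. Without Haunt, the median of its list was -0.18 at day 2 and -0.13 at day 4, where camera no longer passed (adjusted p = 0.263). Camera passed 10, 9, 7, 10 and 13 lists in the 5 comparisons. With an estimated correlation it passed 0 in each (0, 0, 0, 0 and 0), and the directional p of fry passed 2, 3, 0, 14 and 14. The mixed p of fry passed further lists. At day 4 these included HOXB, neural progenitor and RA response (fry mixed adjusted p = 0.0184, 0.0130 and 0.0190). Of the genes given by the rule, direction turned in some fit for 12 of 88 at day 2, 4 of 95 at day 4, 17 of 96 in the interaction, 5 of 104 in WT over time and 8 of 104 in 58 kb KO. A call was lost in some fit for 4, 0, 0, 19 and 27 of them. Of the genes named, Hoxa2 at day 4 ranged from -0.18 to 0.00860 without a library. With the library name as a block, the counts were 4, 0, 0, 4783 and 3705 (2270 and 1282 genes at an unadjusted p under 0.05 where 0). Libraries of 1 name also share shifts along chromosomes at both days, as on chromosome 1 in KO-i, and the reported fit does not use the name. Over all genes, deviations correlated at r = 0.0849 (WT-1 less WT-2) and 0.260 (KO-i less KO-j) between days. Not run were all fits on LIF days 2 and 6, including the cell-line block, the mean of the JF4 libraries and leaving out a library, since those columns are means. The interaction uses all groups, so no fit on fewer was made. Depth limits genes near 1 FPKM most in KO-i at day 2, with 9.05 M reads.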

Other observations

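The tests of the normalization on chromosome 1, of the whole X and of extra copies on the X were chosen only after the result was seen. In the LIF and lineage table the Polycomb list held members that lay far apart in NSC. Cbx7, a chromodomain subunit of the Polycomb repressive complex in ES cells, stood at 22.3 FPKM in the authors' mean at day 0 and at 0.416 in NSC, while Bmi1, a ring-finger subunit needed for neural stem cell renewal, stood at 1.52 at day 0, 35.3 in NSC and 21.5 in NPC. The list's median in NSC was -0.78 over 14 genes, 4 of them more than 2-fold higher and 7 lower. The cyclin gene Ccnd2 went with the neural samples, at 2.31 FPKM at day 0, 234 in NSC and 68.8 in NPC. In the RA table, Cbx7 was 41.4 to 59.4 FPKM and Bmi1 5.60 to 10.1 over all 8 libraries, tables being normalized separately.

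Mid1, an X-linked microtubule-binding ubiquitin ligase gene at the border of the pseudoautosomal region, stood at 0.624 FPKM in the authors' mean at day 0 and 3.29 at day 4, and at 116 in NSC, 259 in ME and 171 in NPC, which come from other ES lines than the LIF columns. Sept7 was listed at 0 in all LIF columns and NSC and at 231 and 238 FPKM in ME and NPC. Nolc1 was listed at 0 at day 2 and in ME and NPC and stood at 94.6 at day 0, and Rpl34 at 1515 at day 0, 17.7 at day 2 and 2051 at day 4. The Y-linked gene Eif2s3y read 21.2 at day 0, 25.7 at day 2, 2.26 at day 4, 26.1 at day 6, 18.7 in ME, 4.00 in NPC and 1.06 in NSC.

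Genes of chromosome 1 were higher in the KO-i libraries, by a median of +0.31 at day 2 and +0.30 at day 4 over 482 genes, and 15 of the 19 shifted windows of KO-i lay there, where at most 2 windows were shifted in 1000 shuffles. The authors' normalization is argued against by the next largest autosomal median of 0.108, on chromosome 14, noise of low values by a median of 0.276 over 220 genes of at least 20 FPKM, and the pace of differentiation by a median of 0.316 over 275 genes that differed by under 0.3 between days in WT. A candidate explanation that stays open is extra copies of the chromosome in part of the cells. Of its genes 74.3% lay above the genome median at both days, where the highest share of another autosome was 41.9%. That share comes from the same values as the shift. It shows how widely the shift is spread and is no separate support for extra copies. Apart from these checks on the expression values, no biological explanation was tested, since no group of the design sets KO-i apart. No DNA data were used here, so the number of copies is not known. In KO-j the 71 genes from position 177531509 of chromosome 1 on, a cut chosen from these values, were shifted by +0.47 at both days. Those of chromosome 6 were shifted by +0.20 and +0.15.

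X-linked genes from position 146832316 on were about 2-fold higher in WT-2 than in WT-1, by medians of +0.99 and +0.89 over 53 genes. The position was picked from these same values as the best cut, so the medians of this segment are selected ones. A difference spread evenly over the whole chromosome is argued against by the 228 other genes, with a median of -0.0349 at the day with the larger value. Noise of low values is argued against by a median of 0.944 over the 21 genes of the segment with at least 20 FPKM. Extra copies of this segment in WT-2 may account for it, since KO-i and KO-j lay at WT-1's level (0.126, -0.0451, 0.0353 and -0.123 in the 4 libraries, on average -0.00179). Apart from these checks on the expression values, no biological explanation was tested, the WT libraries being of 1 group.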
